A study of Mus musculus with 12 samples.

How the data were processed

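Total RNA of isolated mouse colonocytes was labelled with biotin and hybridised to Illumina bead arrays, 1 array per sample, per the labels. There were 6 germfree and 6 conventionally raised samples, grouped and assigned to 2 batches from the labels. The values used are natural log expression values deposited by the authors, 1 row per gene symbol, with a detection p-value for each gene and array deposited beside them. The submitters' processing notes name limma, with no version or role; the normalization, the background correction and the rule that joined probes into genes are not given in the sources used here. The values themselves show that they had been log-transformed and lay at a like level within each batch but not across batches. Array medians lay between 4.34 and 4.35 in batch 1 and between 5.30 and 5.31 in batch 2. The distributions within a batch were not identical: in batch 1 the maximum was 10.1 on conventional replicate 2 and 10.2 on germfree replicate 2. A second deposited table held identical values for the 15132 symbols in both (largest difference 0), so it was not a separate source. The log base is not stated. Read as natural logs, the highest values correspond to signals of 24343 to 56227 units, within the range of a scanner; read as base 2, to 1098 to 1961. A curve with an added background joining the 2 batches left a mean absolute deviation of 0.215 with natural logs and 0.220 with base 2, but the curve fitted best with a factor of 1.57, which matches neither natural logs (a factor of 1) nor base 2 (0.693), so it does not settle the base. The choice rests on the signal range, and every fold value assumes natural logs. The reported p-values and the calls by adjusted p alone do not depend on the base. The counts at 1.5-fold and 2-fold do: 268 and 61 genes would be 109 and 25 with base 2. The background corrections run as alternatives, on exponentiated values, and the shares predicted between batches do depend on it: with base 2 the share was 0.173 for clock and immediate early genes and 0.958 for interferon genes.

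The design, the gene lists and the rule for named genes were fixed before the data were examined. The design had assumed linear intensities and a background correction with quantile normalization as the main step. Because the deposited values were already on a log scale, they were used directly, and the planned correction, applied to the exponentiated values, became an alternative. Of 15154 rows, 15 had symbols turned into dates, and all 15 were restored from the row with identical values in the second table. The symbol of 1 row had been turned into a number and stayed unnamed. Genes with a detection p under 0.05 on at least 3 of the 12 arrays were tested, which left 8122 and excluded 7032. Because the detection p did not always follow the value, the excluded genes included 45 whose values lay at least 1 log unit above background on 12 of 12 arrays. How it was joined over probes is not given.

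Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with batch and group as terms, and p-values were adjusted by Benjamini-Hochberg over the genes tested. The difference is always germfree minus conventional. A batch by group term tested whether it depended on the batch, and the fit was repeated within each batch. In all, there were 41 gene lists and marker lists. The 37 with at least 2 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 37 lists, and again with the correlation estimated per list. They were also tested with fry, which asks whether a list differs between the groups at all, not whether it differs from other genes. Older symbols were matched through a table of mouse RefSeq genes on GRCm38.p6, used for names only.

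The genes named in the text were chosen by a rule. It took the 8 largest rises and the 8 largest falls among genes past an adjusted p of 0.05 with the same sign in both batches, passing over unnamed clones and gene models. It also took 14 genes of energy metabolism, transport, growth and defence whatever they did, of which 6 were tested, the 3 members with the smallest p of each list past 0.05, and the 1 with the smallest p of any other list with a member past it. Genes named outside this rule are said to be, and 3 genes the rule picked are not reported here.

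On simulated arrays made from these genes' means and spreads, the fit of 8122 genes recovered 97 of 100 genes changed by 1.5-fold and 100 of 100 changed by 2-fold between germfree and conventional, with 4 false calls. Each simulated change was equal in both batches, so the recovery does not cover genes whose difference depended on the batch. In a simulation of 37 lists, the list test called the 1 moved list and 1 of the unmoved lists. The simulated genes varied independently of each other. The simulation therefore does not show how the list test behaves when members are correlated. In the data the estimated correlation was 0.403 for the interferon list and 0.771 for the MHC class II list.

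The alternatives were other background corrections and normalizations, no filter and a stricter one (detection p under 0.01 on at least 6 arrays), no batch term, the replicate number as a block, each batch alone, array weights, another variance prior, other thresholds and leaving out each array. The mean over probes was not possible with 1 row per gene, and the second table was not run because its values are identical. The detection p-values reflect signal over background, which limits the values of dim genes: at a batch 1 level under 4.5 log units, genes had a median of 4.03 in batch 1 and 5.21 in batch 2, so differences of dim genes are compressed more in batch 2.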

Results

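Gene expression was measured on Illumina bead arrays in colonocytes, the epithelial cells of the colon, isolated from C57BL/6 mice. The animals had either been kept germfree in isolators, without any microbes, or had been raised conventionally, with a normal gut microbiota. Each group comprised 6 samples, which the labels describe as biological replicates, and each sample was measured on 1 array. The arrays fell into 2 batches named in the labels, each with 3 germfree and 3 conventional samples. Of the 15154 genes with a value, 8122 were above background, that is, had a deposited detection p under 0.05, on at least 3 of the 12 arrays and were tested. The detection p did not always follow the value: on each array, 198 to 374 genes had a detection p of at least 0.05 although their value lay at least 1 log unit above the level of genes at background. The number of genes above background was lower in germfree samples in both batches. It was 7090 to 7136 in germfree against 7353 to 7402 in conventional samples in batch 1, and 6089 to 6238 against 6306 to 6470 in batch 2. The mean difference of -243 genes had an exact permutation p of 0.005 (two-sided, labels exchanged within batches, 400 labelings), the smallest these labelings allow. The number of arrays limits the precision of all values.

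The first comparison asked which genes differ in colonocytes between germfree and conventionally raised mice. In germfree colonocytes the largest falls included Duoxa2, the maturation factor of the dual oxidase Duox2, the antimicrobial lectin Reg3g, the goblet cell protein Retnlb and the interferon-induced gene Ifi27. The largest rises included the brush-border peptidase Anpep, the metallothionein Mt2, the lipoprotein component Apob, the amino acid transporter subunit Slc7a9 and the acute-phase protein Saa1. Duoxa2 was 5.55-fold lower in germfree samples (difference -1.71 ± 0.0938 natural log units, SE, n = 6 per group; adjusted p = 2.07e-07). Anpep was at least 5.22-fold higher (1.65 ± 0.0947, adjusted p = 2.12e-07), by at least 7.15-fold in batch 1 and 3.81-fold in batch 2, since 3 conventional arrays lay near background. In all, 2242 genes differed at an adjusted p under 0.05 (limma, with batch as a term), 1024 higher and 1218 lower in germfree. The median size of these differences was 1.22-fold, 268 genes differed by at least 1.5-fold (125 higher and 143 lower), and 61 by at least 2-fold. With the background correction and quantile normalization first planned, 1762 genes differed (864 genes higher in germfree and 898 genes lower in germfree). With median scaling in place of quantile normalization, 19.4% of the 1862 calls were higher, against 45.7% as reported. All fold values take the deposited log values as natural logs, a base inferred from the values; the calls by adjusted p alone do not depend on it, whereas those after background correction and those at a fold threshold do. With base 2, 109 genes would differ by at least 1.5-fold and 25 by at least 2-fold.

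Among the other large falls, Ckb, the brain-type creatine kinase, was 4.5-fold lower (-1.50 ± 0.112, adjusted p = 2.46e-06), with a detection p under 0.05 on 3 of 6 arrays in either group although its value lay at least 1 log unit above background on 12 of 12 arrays. Ly6a was 3.5-fold lower (adjusted p = 0.00073), Retnlb 3.42-fold (adjusted p = 0.000145), and Capg, an actin-capping protein, 3.09-fold (adjusted p = 1.18e-07). In batch 2 alone Ly6a (2.36-fold, adjusted p = 0.168) and Retnlb (3.02-fold, adjusted p = 0.0686) did not pass. There Ly6a on germfree replicate 5 (0.253 log units from the batch mean) lay above conventional replicates 5 (0.158) and 6 (0.216). Ifi27 was not above background on any germfree array and was at least 2.99-fold lower averaged over both batches (adjusted p = 0.000438), by at least 5.28-fold in batch 1 and 1.7-fold in batch 2. Folds are given as at least where arrays of the lower group had no detection and lay less than 1 log unit above background. Such arrays were set at their lowest detected signal where their own value was dimmer. Where arrays of the higher group lay so as well in the same comparison, the fold is no lower bound and is given as about. The phospholipase Pla2g4c was at least 4.82-fold lower over both batches (adjusted p = 0.00732), by at least 15.6-fold in batch 1. In batch 2 alone it did not pass (-0.407 ± 0.312, adjusted p = 0.52), and this difference was -0.780 without germfree replicate 5, which lay above the conventional mean, -0.240 without conventional replicate 6, and -0.264 and -0.176 without germfree replicates 4 and 6. Among the other large rises, the peptidase Naaladl1 was 4.35-fold higher (1.47 ± 0.119, adjusted p = 4.57e-06; 6.35-fold in batch 1 and 2.98-fold in batch 2), Slc7a9 3.14-fold (adjusted p = 2.12e-07), Apob 3.07-fold (adjusted p = 2e-06) and Saa1 3.06-fold (adjusted p = 7.78e-07). Mt2 was at least 4.46-fold higher (adjusted p = 0.000587), by 10-fold in batch 1 and at least 1.99-fold in batch 2. For the genes chosen by the rule and given as higher or lower, 6 of 6 germfree arrays lay on that side of the conventional mean of their batch, except 5 of 6 for Pla2g4c, Cd14, Rpl22, Osta, Ostb, Gm129, Fosb and Dbp. Some of the genes named in the text had a detection p under 0.05 on only part of the arrays. In conventional and germfree samples these were 6 and 2 of 6 arrays for Pla2g4c, 5 and 5 for Slc7a9, 5 and 6 for Mt2 and Lgr5, 6 and 5 for Mcm6, 6 and 3 for H2-DMb1, 6 and 4 for Elovl6, 4 and 3 for AI451557, 3 and 5 for Gm129, and 5 and 2 for Smtn. For Mcm6, Elovl6 and Slc7a9 the arrays without it still lay at least 1 log unit above background.

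**Figure D1:**
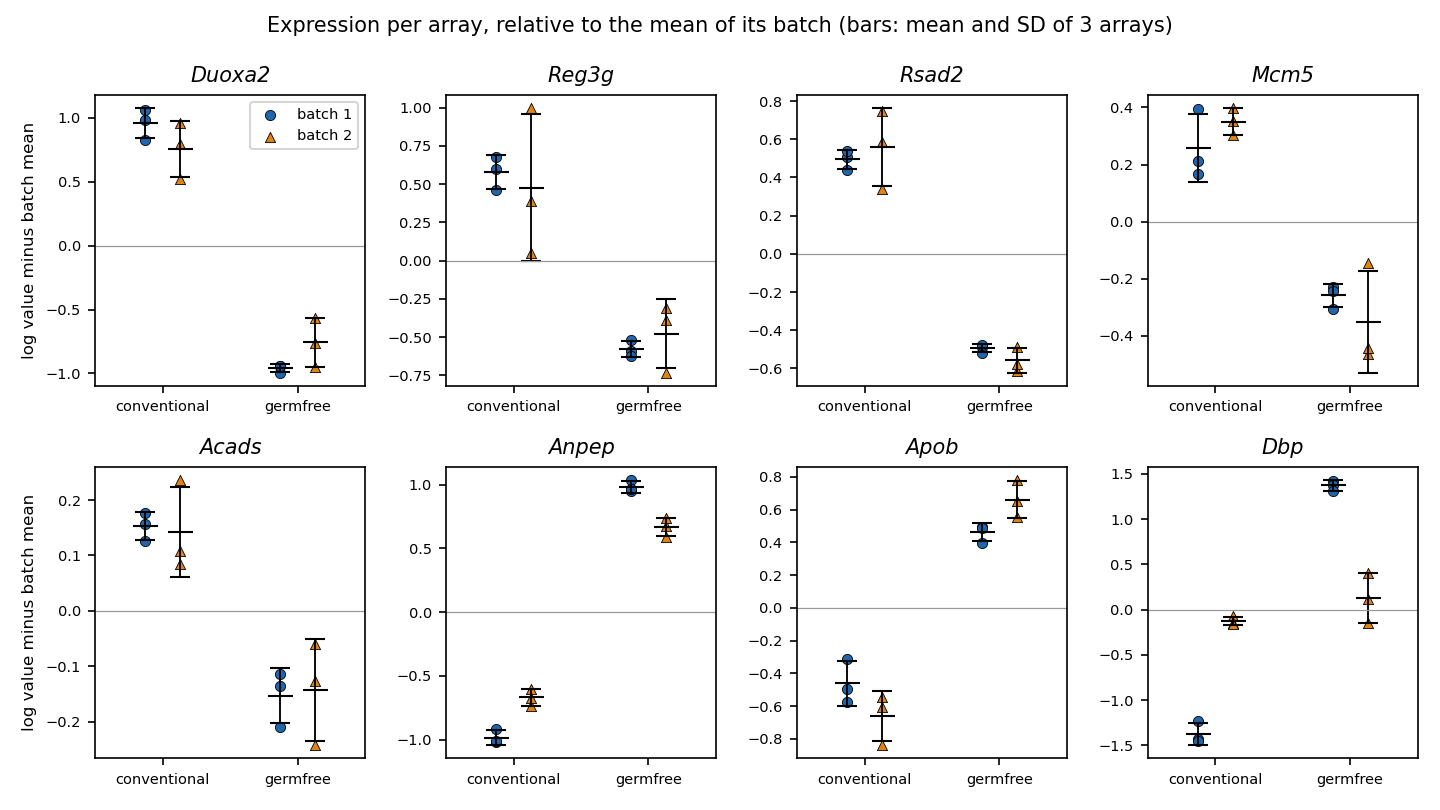
Expression of 8 genes on each array, as the natural log value minus the mean of its batch, for conventional and germfree samples (circles, batch 1; triangles, batch 2; bars, mean and SD of 3 arrays). The groups stand apart in both batches for Duoxa2, Reg3g, Rsad2, Mcm5, Acads, Anpep and Apob, while Dbp differed by 2.74 log units in batch 1 and by 0.256 in batch 2.

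Interferon response genes fell together in germfree colonocytes. Of 21 tested members of this list, 19 were lower, 0 higher and 2 did not pass, and the median member was 1.76-fold lower. Adjusted over the list alone, 20 were lower. The antiviral gene Rsad2 was 2.86-fold lower (-1.05 ± 0.0582, adjusted p = 2.07e-07), the oligoadenylate synthetase Oas2 at least 2.69-fold (adjusted p = 2e-06, above background on 3 of 6 germfree arrays) and the secreted glycoprotein Lgals3bp 1.76-fold (adjusted p = 1.96e-05). The list stood below the other genes in limma's camera test with a preset correlation (adjusted p = 3.24e-14 over 37 lists; adjusted p = 0.169 with an estimated correlation), and 6 of 6 germfree arrays had a lower list mean than the conventional arrays of their batch. It passed in batch 1 (adjusted p = 2.46e-14) and in batch 2 (adjusted p = 1.61e-09).

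Some antigen presentation genes were lower as well. In the MHC class II list, 4 of 9 members were lower, 0 higher and 5 did not pass, 6 being lower when adjusted over the list alone. H2-DMa, which loads peptides onto class II molecules with its partners, was 1.96-fold lower (adjusted p = 0.00379), H2-DMb1 at least 1.85-fold (adjusted p = 0.00691) and H2-DMb2 about 1.67-fold (adjusted p = 0.0128, above background on 4 of 6 conventional and 2 of 6 germfree arrays). The class II list passed at an adjusted p of 0.0212 with the preset correlation, but not with an estimated correlation (adjusted p = 0.713), nor in batch 2 alone (adjusted p = 0.389, against 2.08e-06 in batch 1). In batch 2 the list mean differed by -0.433 log units with all arrays and by 0.00859 without conventional replicate 4, against -0.633 in batch 1. With the background correction first planned neither this list (adjusted p = 0.186) nor H2-DMa, H2-DMb1 and H2-DMb2 (adjusted p = 0.15, 0.273 and 0.206) passed. In the MHC class I list, 4 of 12 members were lower, 0 higher and 8 did not pass, the same numbers as adjusted over the list alone. The peptide transporter Tap1 was 1.62-fold lower (adjusted p = 0.000587) and H2-M3 1.23-fold (adjusted p = 0.00731). The gene listed as AI451557, an older symbol of the class I transactivator Nlrc5, was about 1.23-fold lower (adjusted p = 0.00253, and 0.0514 with the background correction first planned). The class I list had an adjusted p of 0.0222 (adjusted p = 0.638 with an estimated correlation), 0.0207 in batch 1 and 0.241 in batch 2, and did not pass without conventional replicate 4 (adjusted p = 0.0686) or with the background correction first planned (adjusted p = 0.0588). Its mean differed by -0.0891 log units in batch 2, and by -0.0228 there without conventional replicate 4. Of 7 tested markers of lymphocytes, 1 was higher and 2 lower, the same numbers as adjusted over the list alone, including the chemokine Ccl5, 1.78-fold lower (adjusted p = 0.000663).

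Of 21 genes of antimicrobial and mucosal defence, 8 were lower, 3 higher and 10 did not pass; adjusted over the list alone, 11 were lower and 4 higher. Duoxa2 is described above, and Reg3g was 2.88-fold lower (-1.06 ± 0.129, adjusted p = 0.000126), by 3.18-fold in batch 1 and 2.6-fold in batch 2. Saa1 rose, against most members of the list that changed. The list as a whole did not pass (adjusted p = 0.0841; adjusted p = 0.326 with an estimated correlation), with an adjusted p of 0.39 in batch 1 and 0.0153 in batch 2. Under some other settings it passed, for example without a detection filter (adjusted p = 0.0204) or with quantile normalization over all arrays (adjusted p = 0.0366).

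Cell cycle genes fell together in germfree colonocytes. Of 19 tested, 16 were lower, 0 higher and 3 did not pass, with a median of 1.41-fold, and 17 were lower when adjusted over the list alone. The replication licensing factors Mcm5 and Mcm6 were 1.84-fold (-0.609 ± 0.0617, adjusted p = 2.85e-05) and 1.56-fold lower (adjusted p = 1.13e-05), and the mitotic checkpoint kinase Bub1b 1.53-fold (adjusted p = 0.000126). The list passed at an adjusted p of 9.83e-11 (adjusted p = 0.135 with an estimated correlation), in batch 1 (adjusted p = 1.96e-08) and in batch 2 (adjusted p = 1.04e-08), and its mean was lower on 6 of 6 germfree arrays. Among crypt stem and progenitor genes, by contrast, 1 of 5 was higher and 0 lower, and this list did not pass (adjusted p = 0.399). Its member Lgr5, a marker of intestinal stem cells, was at least 1.31-fold higher (adjusted p = 0.00697).

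Some genes of lipid synthesis were lower. In cholesterol synthesis, 5 of 10 tested members were lower, 0 higher and 5 did not pass, 6 being lower when adjusted over the list alone. The decarboxylase Mvd was 1.8-fold lower (adjusted p = 0.000267), Sc4mol, the older symbol of the sterol oxidase Msmo1, 1.45-fold (adjusted p = 0.000819) and the sterol sensor Insig1 about 1.33-fold (adjusted p = 0.000401, above background on 4 of 6 arrays in either group). In fatty acid synthesis, 5 of 8 were lower, 0 higher and 3 did not pass, with the same counts adjusted over the list alone. The desaturases Fads1 and Scd2 were 1.81-fold (adjusted p = 2.02e-05) and 1.54-fold lower (adjusted p = 0.00219), and the elongase Elovl6 1.25-fold (adjusted p = 0.00908). The cholesterol list passed at an adjusted p of 0.00164 (adjusted p = 0.326 with an estimated correlation), with 0.0448 in batch 1 and 0.00041 in batch 2, and the fatty acid synthesis list at 0.0212 (adjusted p = 0.169 with an estimated correlation). The second of these did not pass in batch 1 alone (adjusted p = 0.259, against 0.00114 in batch 2).

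Energy metabolism was examined because colonocytes take much of their energy from the oxidation of butyrate, a product of gut bacteria. Single enzymes of energy metabolism were lower in germfree samples. Acads, the dehydrogenase of short-chain acyl-CoA, was 1.34-fold lower (-0.295 ± 0.0388, adjusted p = 0.000222), by 1.36-fold in batch 1 and 1.33-fold in batch 2. The tricarboxylic acid cycle enzymes Mdh2 and Fh1 were 1.31-fold (-0.267 ± 0.0841, adjusted p = 0.0318) and 1.24-fold lower (adjusted p = 0.00413), and Cycs, cytochrome c, 1.27-fold (adjusted p = 0.000587). Mdh2 did not pass without conventional replicate 1, 3 or 4 or without germfree replicate 1, 2, 3 or 4 (adjusted p = 0.0534 to 0.0726), nor with the background correction first planned (adjusted p = 0.0835). The medium-chain enzyme Acadm (0.0523 ± 0.0441 log units, adjusted p = 0.412) and Sdhb (-0.105 ± 0.0435, adjusted p = 0.0936) did not pass. Sdhb passed without conventional replicate 5 (adjusted p = 0.0393) or germfree replicate 5 (adjusted p = 0.0325). It also passed in batch 1 alone (-0.213, adjusted p = 0.00113), and the batch by group term passed for it (adjusted p = 0.0307).

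As lists, none of the 3 energy pathways passed over both batches. Fatty acid oxidation had 7 of 15 members lower and 1 higher (adjusted p = 0.0534; adjusted p = 0.393 with an estimated correlation), the tricarboxylic acid cycle 4 of 15 lower and 1 higher (adjusted p = 0.113; adjusted p = 0.713 with an estimated correlation), and oxidative phosphorylation 7 of 49 lower and 2 higher (adjusted p = 0.113; adjusted p = 0.776 with an estimated correlation). Adjusted over the list alone, the lower and higher members numbered 8 and 1, 4 and 1, and 6 and 2. In the list test, TCA cycle (tricarboxylic acid cycle) genes passed without germfree replicate 5 (adjusted p = 0.0319) and oxidative phosphorylation without conventional replicate 5 (adjusted p = 0.0339) or germfree replicate 5 (adjusted p = 0.0229). Fatty acid oxidation passed without conventional replicate 2 or 4 or germfree replicate 4 or 6 (adjusted p = 0.0371 to 0.0487). All 3 passed in batch 1 alone (adjusted p = 0.026, 0.0207 and 0.00846) and none in batch 2 alone (adjusted p = 0.53, 0.879 and 0.927). The difference between the batches itself passed for oxidative phosphorylation (adjusted p = 0.0266; adjusted p = 0.643 with an estimated correlation), not for fatty acid oxidation (adjusted p = 0.221) or the tricarboxylic acid cycle (adjusted p = 0.0907). Glycolysis had 1 of 11 members lower, Gapdh by 1.18-fold (adjusted p = 0.00595), and 0 higher. In pyruvate entry 2 of 7 were higher and 2 lower, the pyruvate dehydrogenase kinase Pdk2 being 1.35-fold higher (adjusted p = 0.00103). In ketone body metabolism 1 of 4 was higher and 1 lower, and Oxct1, which activates ketone bodies for oxidation, was 1.35-fold higher (adjusted p = 0.00392). Among autophagy genes 2 of 14 were higher and 1 lower, with Atg16l1 1.25-fold higher (adjusted p = 0.000619). The lists of glycolysis, pyruvate entry, ketone body metabolism and autophagy did not pass (adjusted p = 0.287, 0.802, 0.776 and 0.287). Slc16a1, Slc5a8 and Cdkn1b did not pass the detection filter. The values of Slc5a8, a monocarboxylate transporter, nevertheless lay at least 1 log unit above background on 12 of 12 arrays, and without the filter it was lower (-0.404 ± 0.11, adjusted p = 0.0266), whereas Slc16a1 and Cdkn1b lay near background. The genes Idh3a, Cpt1a, Pdk4, Map1lc3b and Reg3b were not analysed here.

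Genes characteristic of the small intestine were higher in germfree colonocytes. Of 11 tested, 7 were higher, 0 lower and 4 did not pass, the same numbers as adjusted over the list alone. Besides Anpep (above background on 3 of 6 conventional arrays) and Apob, the retinol-binding protein Rbp2 was 1.98-fold higher (adjusted p = 0.000221). The brush-border phosphatase Alpi, chosen after its values were seen, did not differ beyond the spread (-0.0534 ± 0.0508, adjusted p = 0.473). The list passed at an adjusted p of 0.000203 (adjusted p = 0.135 with an estimated correlation), in batch 1 (adjusted p = 0.000143) and in batch 2 (adjusted p = 0.000747), and its mean was higher on 6 of 6 germfree arrays. Conventional replicate 1 stood apart from the other conventional arrays of its batch (list mean -0.00909 against -0.428 and -0.442). This came mostly from Apoa1 and Apoc3, chosen after their values were seen, which lay 1.37 and 1.51 log units above their group mean there, with Apob (0.150) and 2010204N08Rik (0.0863, likewise chosen after its values were seen) slightly above it and Anpep (-0.0365) and Rbp2 (-0.0309) slightly below.

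Some bile acid and ion transport genes rose as well. Among bile acid genes, 3 of 5 were higher, 0 lower and 2 did not pass, the same numbers as adjusted over the list alone. The ileal bile acid binding protein Fabp6 was 2.76-fold higher (1.02 ± 0.195, adjusted p = 0.00243), by 5.23-fold in batch 1 and 1.46-fold in batch 2 (1.25-fold there without germfree replicate 5), and the transporter subunits Osta and Ostb were 1.63-fold (adjusted p = 0.0283) and 1.42-fold higher (adjusted p = 0.00442). Osta did not pass without any 1 of conventional replicates 1 to 4 or germfree replicates 1, 2, 3, 4 and 6 (adjusted p = 0.0502 to 0.0668), nor with the background correction first planned (adjusted p = 0.0552). This list passed at an adjusted p of 0.0303 (adjusted p = 0.343 with an estimated correlation), with 0.00348 in batch 1 and 0.241 in batch 2, and not without conventional replicate 3 (adjusted p = 0.0513) or with the background correction first planned (adjusted p = 0.0588). Among genes of ion and monocarboxylate transport, 8 of 15 were higher, 1 lower and 6 did not pass, 9 being higher and 1 lower when adjusted over the list alone. The enzyme Hsd11b2, which protects the mineralocorticoid receptor from glucocorticoids, was 1.5-fold higher (adjusted p = 0.00113) and the carbonic anhydrase Car4 1.4-fold (adjusted p = 0.00168). The transport list passed at an adjusted p of 0.00964 (adjusted p = 0.326 with an estimated correlation), with 0.0763 in batch 1 and 0.00198 in batch 2, and not without a batch term (adjusted p = 0.0878). In batch 2 its mean difference was 0.177 log units, and 0.0879 without germfree replicate 5.

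Enteroendocrine cell markers were higher: 5 of 9 rose, 0 fell and 4 did not pass, 6 being higher when adjusted over the list alone. Gcg, the glucagon precursor, was 1.95-fold higher (0.669 ± 0.0941, adjusted p = 0.000334), the hormone Cck 1.77-fold (adjusted p = 0.0015) and the secretory chaperone Scg5 1.26-fold (adjusted p = 0.00504). The list passed at an adjusted p of 0.00164 (adjusted p = 0.343 with an estimated correlation). It passed in batch 1 (adjusted p = 2.08e-06) and not in batch 2 (adjusted p = 0.35), and the batches differed (adjusted p = 0.000656).

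Clock genes and immediate early genes differed more between the groups in batch 1 than in batch 2. Dbp, a clock-controlled transcription factor, was 15.5-fold higher in germfree samples in batch 1 and 1.29-fold in batch 2 (4.48-fold over both, adjusted p = 0.00787; difference between batches, adjusted p = 7.05e-07). Gm129, the older symbol of the clock repressor Ciart, was at least 3.49-fold higher in batch 1, where no conventional array was above background, and 1.15-fold in batch 2, and the immediate early genes Fosb and Ier2 were 9.42-fold and 2.74-fold higher in batch 1 against 1.38-fold and 1.21-fold in batch 2. None of these 4 passed in batch 2 alone. There, without germfree replicate 5, Dbp was 1.48-fold, Gm129 1.26-fold and Fosb 1.73-fold higher; without germfree replicate 4, Dbp was 1.12-fold and Gm129 1.07-fold, and without germfree replicate 6, Fosb was 1.14-fold. Arntl, the activator at the centre of the clock and chosen after its values were seen, was lower in batch 1 (-1.64 log units) and not in batch 2 (0.198), which left it short of the threshold over both (adjusted p = 0.0565). Of 9 clock genes 6 were higher, 0 lower and 3 did not pass, and adjusted over the list alone 6 were higher and 2 lower (list adjusted p = 0.0253; adjusted p = 0.343 with an estimated correlation). Of 13 immediate early and heat shock genes 7 were higher and 2 lower in either adjustment (list adjusted p = 0.0298; adjusted p = 0.713 with an estimated correlation). The chaperone partner Dnajb1 was 1.44-fold higher (adjusted p = 0.00174) and the chaperone Hsp90aa1 about 1.31-fold lower (adjusted p = 0.000213, with a detection p under 0.05 on 4 of 6 arrays in either group although its value lay at least 1 log unit above background on 6 of 6 arrays of batch 1). For both lists the batches differed (adjusted p = 0.000673 and 2.34e-09). The clock list passed in each batch (adjusted p = 0.00598 and 0.00785) and its mean was higher on 6 of 6 germfree arrays. The immediate early list passed in batch 1 (adjusted p = 5.19e-07) and not in batch 2, where its direction turned (adjusted p = 0.746), and was higher on 4 of 6 germfree arrays. In batch 2 its mean difference was -0.0755 log units, and 0.00437 without germfree replicate 5. Without conventional replicate 1 or 3 or germfree replicate 2 or 3 it did not pass (adjusted p = 0.0525 to 0.0669), nor with the background correction first planned (adjusted p = 0.0689).

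**Figure D2:**
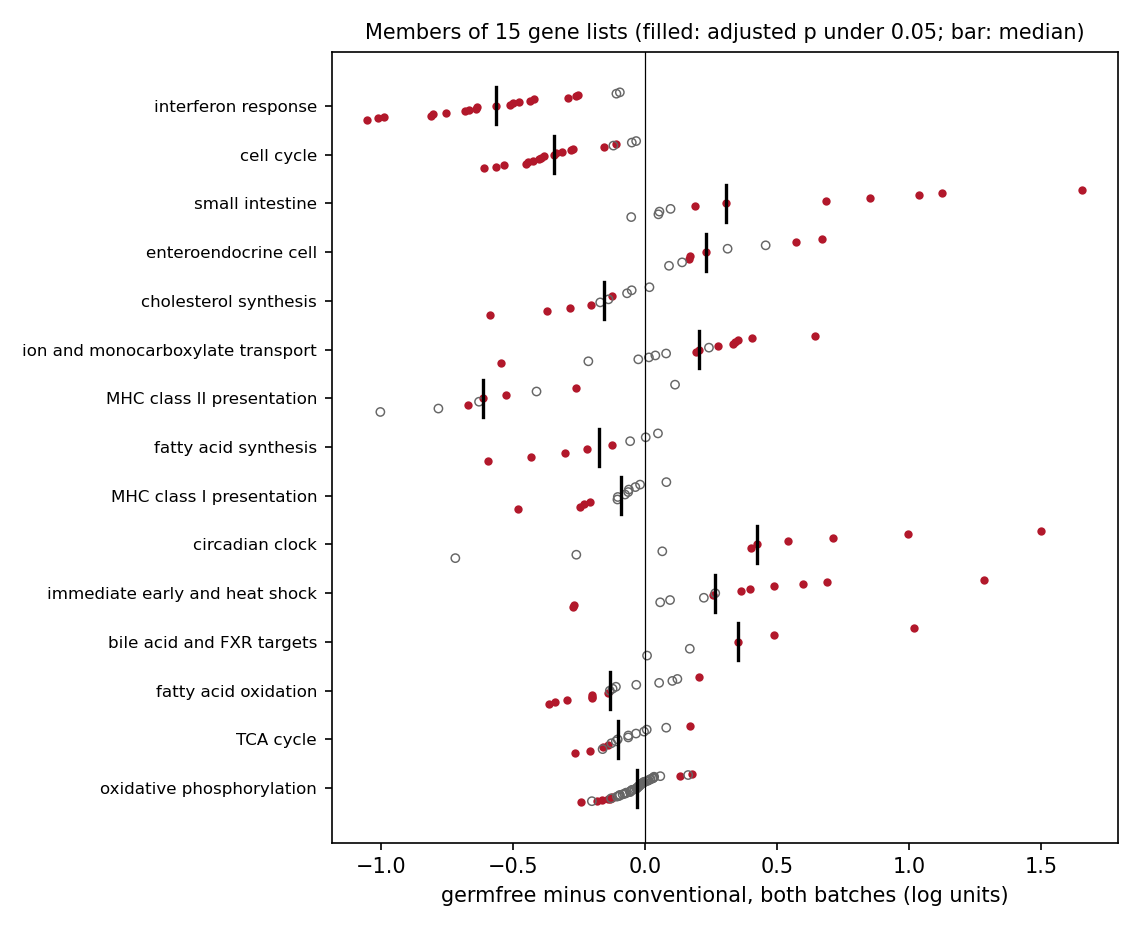
Germfree minus conventional difference over both batches, in natural log units, for the tested members of 15 gene lists (filled points, adjusted p under 0.05; open points, not past it; bars, the list's median). Nearly all interferon response and cell cycle members lie below 0, with 19 of 21 and 16 of 19 past the threshold, while the oxidative phosphorylation members lie around 0, with 7 of 49 lower and 2 higher.

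The lists of the unfolded protein and amino acid response, peroxisome proliferator-activated receptor targets, xenobiotic metabolism and ribosomal proteins did not pass (adjusted p = 0.236, 0.529, 0.588 and 0.459). Of their 12, 12, 26 and 13 tested members, 2, 0, 7 and 2 were higher and 4, 2, 4 and 0 lower. Adjusted over the list alone, 2, 0, 7 and 0 were higher and 5, 1, 4 and 0 lower. Their member with the smallest p was Psat1, an enzyme of serine synthesis, 1.4-fold lower (adjusted p = 4.11e-05), the lipid droplet protein Adfp, 1.2-fold lower (adjusted p = 0.0105), the cytochrome P450 Cyp3a13, 2.07-fold higher (adjusted p = 2.12e-07), and Rpl22, 1.21-fold higher (adjusted p = 0.0325). Rpl22 did not pass without conventional replicate 1, 2, 3 or 5 or germfree replicate 1, 2 or 3 (adjusted p = 0.0564 to 0.0767), nor with the background correction first planned (adjusted p = 0.0517). In the list test, the unfolded protein and amino acid response passed in batch 2 alone (median -0.266 log units, adjusted p = 0.00041). In batch 1 its median had the other sign and it did not pass (0.0807, adjusted p = 0.572). Markers of absorptive colonocytes, the main cell type of the preparation, did not pass as a list (adjusted p = 0.872, 1 of 11 higher and 2 lower), nor did those of goblet cells (adjusted p = 0.454, 5 of 11 higher and 1, Galnt12, lower by 1.35-fold with an adjusted p of 0.00354) or tuft cells (adjusted p = 0.872, 1 of 6 higher, Avil by 1.15-fold with an adjusted p of 0.00329). The goblet cell list passed the list test in batch 1 alone (median 0.176 log units, adjusted p = 0.0207) and not in batch 2 (-0.0386, adjusted p = 0.55). Of lists for cells outside the epithelium, lymphocytes (adjusted p = 0.667), myeloid cells (adjusted p = 0.872), mast cells (adjusted p = 0.872), fibroblasts (adjusted p = 0.872), smooth muscle (adjusted p = 0.872), endothelium (adjusted p = 0.667), adipocytes (adjusted p = 0.861) and exocrine pancreas (adjusted p = 0.802) did not pass, nor did genes of the distal colon (adjusted p = 0.44). The members with the smallest p of their list, where past the threshold, were Cd14, 1.44-fold lower (adjusted p = 0.0166, and 0.0537 with the background correction first planned), the smooth muscle gene Smtn, at least 1.5-fold lower (adjusted p = 4.48e-05), and the endothelial gene Egfl7, not above background on any germfree array and about 1.06-fold lower (adjusted p = 0.0303). Egfl7 did not pass without conventional replicate 1 or 3 or germfree replicate 1, 3 or 4 (adjusted p = 0.0505 to 0.0695), nor with the background correction first planned (adjusted p = 0.105). Other members past the threshold, chosen after their values were seen, went both ways. The myeloid gene Cd68 was higher (0.424 ± 0.123, adjusted p = 0.0223, with 0.845 in batch 1 and 0.00334 in batch 2). So was the lymphocyte gene Xcl1 over both batches (0.332 ± 0.112, adjusted p = 0.043), with 0.705 in batch 1 and the other sign in batch 2 (-0.0418). The smooth muscle gene Mylk was higher (0.367 ± 0.093, adjusted p = 0.0115), while the lymphocyte gene Cd8b1, above background on 3 of 12 arrays, was lower (-0.281 ± 0.0599, adjusted p = 0.00453). Lists of B and plasma cells, erythroid cells, enteric neurons and glia, and sex-linked genes had fewer than 2 tested members and no test. The median, the mean and the test did not share a sign for absorptive colonocytes, xenobiotic metabolism, smooth muscle, tuft cells and fibroblasts, all with small medians. Of the 12 lists past the threshold with the preset correlation, 0 passed with an estimated correlation, and the preset test also passed a median of 5 lists in 99 other splits of the same arrays. The mean of each of the 12 lists lay on its side on 6 of 6 germfree arrays, except 4 of 6 for the immediate early list. For MHC class II in batch 2 this rested on conventional replicate 4, as given above. Agreement of 6 of 6 does not set these lists apart. Lists that did not pass, among them fatty acid oxidation, antimicrobial defence, autophagy and absorptive colonocytes, also had all 6 germfree arrays on the same side.

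The second comparison asked whether the difference between germfree and conventional samples depended on the batch. Among the 2242 genes called over both batches, 2205 (98.3%) had the same sign in batch 1 and in batch 2, and 37 had opposite signs, although calling on the mean of both batches favours genes of 1 sign. Across all genes tested, the 2 batches' differences had a Pearson correlation of 0.434 and a Spearman correlation of 0.358; genes are not independent replicates. Alone, batch 1 gave 3810 genes (1782 higher and 2028 lower) and batch 2 gave 337 (141 higher and 196 lower). They shared 244 genes, 221 of them in the same direction, where independent lists of these sizes would share 79.9 in the same direction. The batch by group term passed for 1441 genes: 1152 of these differed more in batch 1, and 877 had opposite signs in the 2 batches. The median residual SD was 0.0499 log units in batch 1 and 0.0731 in batch 2, and the level of genes at background, on the natural log reading, was 54.1 to 56.8 signal units in batch 1 and 182 to 183 in batch 2. Of the 2242 genes, 1689 did not pass the batch by group term.

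**Figure D3:**
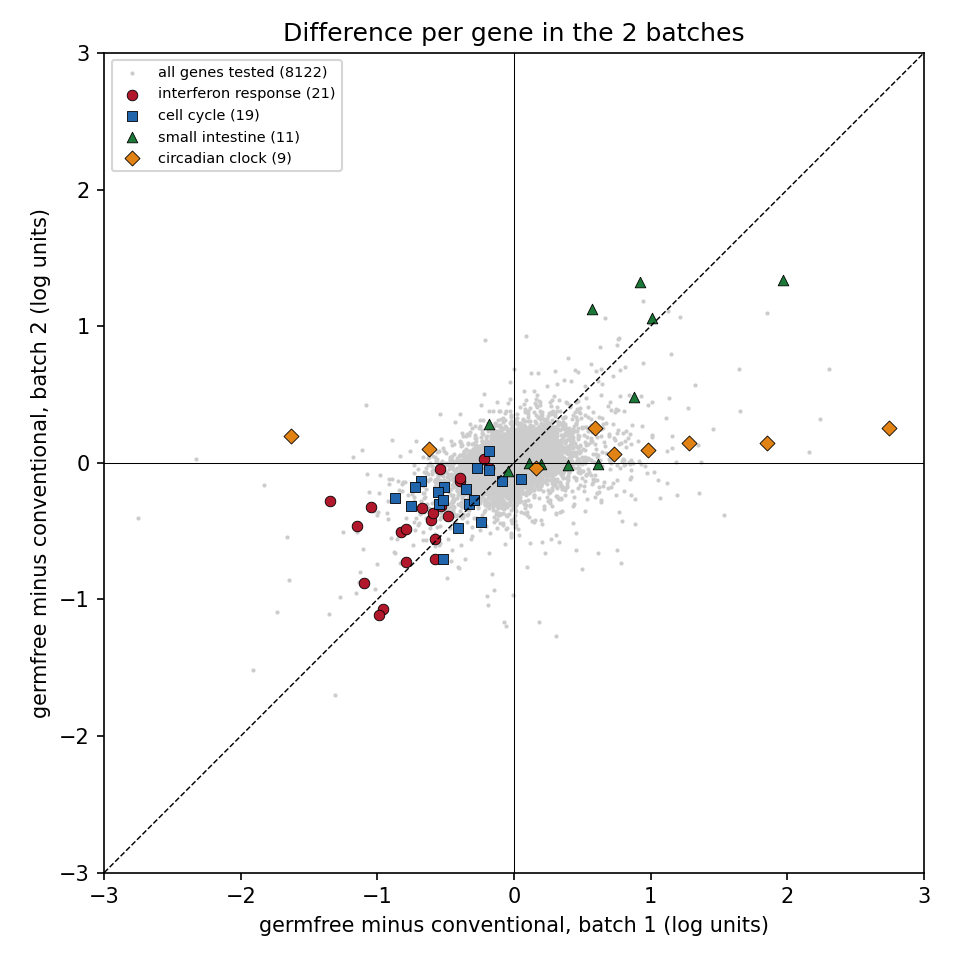
Germfree minus conventional difference of each of the 8122 genes in batch 1 (horizontal axis) and in batch 2 (vertical axis), in natural log units, with the members of 4 gene lists marked and the line of equal differences dashed. Interferon response members lie below 0 in both batches for 20 of 21, whereas clock genes spread along the horizontal axis, with Dbp at 2.74 in batch 1 and 0.256 in batch 2.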

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

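The tests of the clock, interferon and small intestine patterns were chosen after the values were seen, except the test of a varying share of small intestinal cells over the whole list; the counts over other splits of the samples were planned.

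Clock and immediate early genes stood out because their germfree minus conventional difference itself differed between the batches (adjusted p = 0.000673 for the clock list and 2.34e-09 for immediate early and heat shock genes). Compression by the higher background of batch 2 is argued against as the whole cause, with the limits given below. Over the 22 tested members, the batch 2 difference was a median share of 0.174 of what the batch 1 difference predicts when both batches are joined by a curve with an added background (95% bootstrap interval -0.115 to 0.269), whereas the 21 interferon genes reached 1.00 (0.703 to 1.08) and the 19 cell cycle genes 0.534 (0.434 to 1.10). The intervals resample genes measured on the same arrays, so they hold no spread between arrays. The shares given here use the curve at the factor of natural logs, which left a mean absolute deviation of 0.215. The curve fitted best at a factor of 1.57, where no share was computed. The clock and immediate early lists were picked because their difference depended on the batch, which favours a low share. Another time of day or handling of the groups in batch 1 remains a candidate explanation: in batch 1, 7 of 7 phased clock genes moved with their known phase, Dbp, Tef, Per1, Nr1d2 and Gm129 up and Arntl and Npas2 down, against 4 of 7 in batch 2. The count took whichever direction gave more genes, so 4 of 7 is the lowest value it can take. The labels used here give no time of collection, and an effect of germfree life on the clock stays open, untested.

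The interferon response list differed in size between the batches (adjusted p = 0.000656; adjusted p = 0.537 with an estimated correlation). A difference in only 1 batch is argued against, because 20 of 21 members were lower in germfree samples in both. Fewer immune cells in the germfree preparations could account for part of the fall and cannot be told apart from a change within the colonocytes. The 11 tested lymphocyte and myeloid markers had a median difference of -0.0124, against -0.566 for the interferon list, but only 2 of them, Ccl5 and Cd14, lay at least 1 log unit above background in both batches, and both were lower. A response of the epithelium itself to the microbiota stays open as the biological explanation.

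Small intestine genes were higher in germfree samples in both batches. A share of small intestinal cells that varied between preparations would make the members rise and fall together. Over the list as a whole this was not seen. The mean pairwise correlation of the 11 members' deviations from their batch and group means was -0.00189. This lay at the 51.1st percentile of 10000 random lists of that size (95th percentile 0.108). The mean weighs all 11 members alike, so it cannot exclude a varying share that shows in only a few of them. A varying share stays open for Apoa1 and Apoc3, whose deviations correlated at 0.779. That correlation rested on the conventional arrays of batch 1, above all conventional replicate 1, where they lay 1.37 and 1.51 log units above their group mean. There Apob (0.150) lay slightly above its mean, and Anpep (-0.0365) and Rbp2 (-0.0309) did not follow. On germfree replicates 4, 5 and 6 they parted (Apoa1 -0.395, 0.958 and -0.563, Apoc3 0.177, -0.102 and -0.0751). A share equal in every germfree array may still contribute and cannot be told apart from a change within the colon, since 7 of 11 members were higher and no small intestinal sample gives the levels such a share would bring. A change of the colonic epithelium without microbes was not tested separately.

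Other lists whose difference depended on the batch were the cell cycle (adjusted p = 0.00748), enteroendocrine markers (adjusted p = 0.000656), oxidative phosphorylation (adjusted p = 0.0266), the unfolded protein and amino acid response (adjusted p = 0.000673), crypt stem and progenitor genes (adjusted p = 0.025) and goblet cell markers (adjusted p = 0.000105). With an estimated correlation 4 lists passed in place of 9: enteroendocrine markers, clock, immediate early and heat shock, and goblet cell markers (adjusted p = 0.0354 each). Oxidative phosphorylation did not (adjusted p = 0.643 with an estimated correlation). Over single genes, the batch by group term passed for 1441.

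In 210 groups of 6 arrays (68 genes and 37 lists, values centred on their batch), 23 had a lone array whose gap to the nearest other, as a share of the group's range, was over Dixon's 95% critical value. About 1 in 20, or 10.5, would be flagged by chance in independent groups of like arrays. The batches differ in spread (median residual SD 0.0499 and 0.0731) and lists and genes overlap, so 10.5 is a rough guide. Apart from germfree replicate 2, every flagged array was of batch 2. Of the 23, 14 concerned germfree replicate 5. It was highest for Ly6a (0.861), H2-DMb1 (0.63), Cd14 (0.733), pyruvate entry (0.656), glycolysis (0.641), MHC class II (0.841) and ion and monocarboxylate transport (0.643), and lowest for Elovl6 (0.652), Scg5 (0.64), Osta (0.778), Gcg (0.802), peroxisome proliferator-activated receptor targets (0.727), ketone body metabolism (0.747) and bile acid genes (0.654). Conventional replicate 6 was lowest for Oas2 (0.819) and the interferon list (0.727) and highest for Mvd (0.705) and antimicrobial defence (0.73). Conventional replicate 5 was lowest for Insig1 (0.732) and highest for peroxisome proliferator-activated receptor targets (0.646). Conventional replicate 4 was highest for Oxct1 (0.65), germfree replicate 4 lowest for antimicrobial defence (0.636) and germfree replicate 2 lowest for MHC class I (0.636).

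Chance alone is an unlikely source of the count of 2242 genes: 1 of 100 splits of the 12 arrays, the real one, gave as many, and the highest other gave 11. The same held for the 1024 higher and the 1218 lower genes (1 of 100 each, highest other 6 in either direction). For the 12 lists, 4 of 100 splits gave as many, the highest other split also gave 12, and the other splits passed a median of 5. Not all splits held 3 arrays of each group in each batch, as the design does. Besides the real split, 1 that did also gave 12. This count therefore does not exclude chance for the number of lists. For 3 lists, interferon response, cell cycle and small intestine, 1 of 100 splits, the real one, gave a p as small; for the clock list 5 did, for cholesterol synthesis 10, for enteroendocrine markers and ion and monocarboxylate transport 11 each, for fatty acid synthesis 13, for bile acid genes 16, for MHC class I 22, and for MHC class II and immediate early genes 37 each. For these 9 lists taken singly, chance is not excluded. For the 3 lists, 1 of 100 is the lowest share these splits allow, and it is not adjusted for the 37 lists tested. For the 1441 batch-dependent genes, 5 of 100 regroupings within batches gave as many (highest other 1866), so chance is not excluded by this count. The count decides little, since the 4 others kept the real groups of batch 1, and with them its difference; the highest of the regroupings without the real batch 1 groups was 19. Within a batch, 10 splits are too few for a share under 0.05: batch 1 gave 3810 genes against 0 in the highest other split, and batch 2 gave 337 against 0 (1 of 10 splits each).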

How the results depend on the processing

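Background correction by detection p with quantile normalization, first planned as the main step, became an alternative after the data were seen, and quantile normalization within each batch was added then; all other settings were planned. The mean over probes and the second table were not run, since there is 1 row per gene and the tables hold identical values. The 2242 genes different between germfree and conventional, 1024 genes higher in germfree and 1218 genes lower in germfree, became 57 (19 and 38) with no batch term, whose variance then holds the difference between batches, 3810 (1782 and 2028) in batch 1 only, 337 (141 and 196) in batch 2 only, 3880 (1866 and 2014) with array quality weights, 1135 (490 and 645) at an adjusted p under 0.01, and 268 (125 and 143) with at least 1.5-fold. Background correction by detection p with median scaling gave 362 higher genes, 19.4% of its 1862 calls against 45.7% as reported; the cause was not tested. The replicate number does not pair the samples: the deviations of same-numbered arrays correlated between -0.355 and 0.0433, and only 1 of 6 correlated best with its own number. With that number as a block, the count was 1335 (582 and 753). Leaving out each array in turn gave 1666 to 2509 genes (lowest without germfree replicate 1, highest without germfree replicate 5), and 1658 to 2102 of the reported genes kept their call. Under the other settings the counts stayed within 1.5 times. The 12 lists became 0 with the correlation estimated per list, 17 with fry, which does not compare a list with other genes, 8 to 15 under the other settings, and 10 to 14 with an array left out. The 1441 genes whose difference depends on batch became 840 with quantile normalization over all arrays; the cause was not tested.

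Interferon response, cell cycle, small intestine and cholesterol synthesis passed under every setting except the estimated correlation. Background correction by detection p with quantile normalization, the step first planned, kept 8 of the 12 lists and ended the calls of MHC class I (0.0588), MHC class II (0.186), bile acid (0.0588) and immediate early genes (0.0689). No batch term ended that of ion and monocarboxylate transport (0.0878), median scaling that of MHC class II (0.408), and fry those of MHC class II (0.0682) and immediate early genes (0.120). The immediate early list turned direction in batch 2 only (adjusted p = 0.746) and lost its call without conventional replicate 1 (0.0669) or 3 (0.0525) and germfree replicate 2 (0.0639) or 3 (0.0551). Without conventional replicate 4 the MHC class I list lost its call (0.0686), and without conventional replicate 3 the bile acid list (0.0513). The stricter detection filter ended the calls of the circadian clock (0.0764), MHC class I (0.0655) and MHC class II (0.0778) lists, and no filter that of the bile acid list (0.125). In the list test, fatty acid synthesis lost its call with array weights (0.0942). Oxidative phosphorylation turned direction in batch 2 only (adjusted p = 0.927), passed without germfree replicate 5 (0.0229) or conventional replicate 5 (0.0339), with array weights (0.0194) and with median scaling (0.00552). In the list test, TCA cycle genes passed without germfree replicate 5 (0.0319), with array weights (0.0335) and with median scaling (0.0169). In the list test, fatty acid oxidation, close to the threshold, passed without conventional replicate 2 (0.0482) or 4 (0.0487) and germfree replicate 4 (0.0393) or 6 (0.0371), with median scaling (0.0448), no detection filter (0.0204), no batch term (0.00985), array weights (0.0367) and fry (0.0053). The antimicrobial list passed with normexp and quantile (0.0338), quantile over all arrays (0.0366), no detection filter (0.0204), no batch term (0.0154) and in batch 2 only (0.0153). Of the 68 named genes, 55 lost their call with no batch term and 42 in batch 2 only. No batch term left the calls of Duoxa2, Retnlb, Capg, Ifi27, Mcm5, Mcm6, Saa1, Apob, Slc7a9, Naaladl1 and Anpep. Batch 2 only left these except Retnlb, and those of Ckb, Rsad2, Oas2, Fads1, Mvd, Lgals3bp, Smtn, Sc4mol, Psat1, Hsp90aa1, Adfp, Hsd11b2, Cyp3a13 and Mt2. The step first planned ended 9: H2-DMa (0.150), H2-DMb1 (0.273), H2-DMb2 (0.206), Cd14 (0.0537), Mdh2 (0.0835), AI451557 (0.0514), Egfl7 (0.105), Rpl22 (0.0517) and Osta (0.0552). Background correction with median scaling ended 10: H2-DMa, H2-DMb1, H2-DMb2, Mdh2, Egfl7, Avil, Rpl22, Atg16l1, Oxct1 and Osta. The replicate block ended 6: H2-DMb2, Cd14, Mdh2, Egfl7, Rpl22 and Osta. H2-DMb2 also lost its call with normexp (0.0548) and with quantile over all arrays (0.0542), and Adfp with array weights (0.0668) and, like Egfl7, in batch 1 only. Sdhb gained a call in batch 1 only (-0.213, adjusted p = 0.00113) and turned sign in batch 2 only (0.00342). Acadm turned sign with median scaling (-0.021) and in batch 1 only (-0.0445). Neither had passed over both batches.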

Other observations

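Several changed genes outside the fixed lists, or not named by their rule, were chosen after their values were seen. Some cytochromes P450 were higher in germfree colonocytes: Cyp2d9 by 1.06 ± 0.121 log units (SE, n = 6 per group, limma adjusted p = 7.03e-05), Cyp2d10 by 0.759 ± 0.0721 (adjusted p = 1.96e-05), Cyp2d26 by 0.808 ± 0.0856 (adjusted p = 4.14e-05) and Cyp4f14 by 0.864 ± 0.0687 (adjusted p = 4.2e-06). Near-identical Cyp2d genes can share transcripts read by 1 probe, so the single genes are uncertain. Cyp2d26 and Cyp4f14 belong to the xenobiotic list, which did not pass. The metallothionein Mt1 was higher by 1.00 ± 0.0542 (adjusted p = 2.07e-07), with 0.986 in batch 1 and 1.02 in batch 2, while the zinc importer Slc39a4 was lower (-0.668 ± 0.0954, adjusted p = 0.000369). The peptidases and hydrolases of the brush border Xpnpep2 (0.803 ± 0.101, adjusted p = 0.000155) and Treh (0.85 ± 0.176, adjusted p = 0.00381) were higher, each more in batch 1 (1.13 and 1.45) than in batch 2 (0.471 and 0.246), and the batch by group term passed for each (adjusted p = 0.000194 and 1.36e-05). Treh was above background on 5 of 6 conventional arrays.

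Among defence genes, Nfkbiz, a regulator of NF-kB target genes, was lower (-0.971 ± 0.0471, adjusted p = 1.18e-07), with -1.01 in batch 1 and -0.927 in batch 2. Itln1, a lectin that binds microbial sugars, was lower (-0.708 ± 0.0753, adjusted p = 4.19e-05, above background on 4 of 6 germfree arrays). The phospholipase Pla2g2a was not above background on any germfree array and was at least 1.73-fold lower (adjusted p = 2.91e-05), while lysozyme, listed as Lyz, was higher (0.568 ± 0.0832, adjusted p = 0.000435). Interferon-inducible genes outside the fixed list, Ifi47 (-0.831 ± 0.132, adjusted p = 0.000691) and Ifitm3 (-0.676 ± 0.059, adjusted p = 1.02e-05), were lower as well.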
